A study of Mus musculus with 2 samples.

How the data were processed

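Gene expression was measured in mouse 5cc7 T cells, which carry a T cell receptor that recognises a peptide of moth cytochrome c. Per the labels, the cells had been stimulated in culture with this peptide, written MCC there, and their RNA was taken 5 days later, when the cells were blasts, the enlarged dividing form of an activated lymphocyte. Per the labels, biotin was the label and the molecule was polyadenylated RNA. The design text records that complementary RNA was made and applied to 2 Affymetrix mouse 430 2.0 arrays, each of which carries short oligonucleotide probes grouped into probe sets. The arrays are called set 1 and set 2 here, as in their titles. They form 1 group, so there was no treated, resting or time-matched control to compare with. The descriptions of both arrays call them experiment 1 of 2, and nothing in the labels says that they hold RNA of separate cultures, so the spread between them may be technical.

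The deposited values are intensity values on a linear scale, 1 per probe set and array, with 1 decimal. The linear scale was read from the values, which ran from 0 to 8860.2 with none below 0. The background correction, probe summary and scaling that the authors used are not given in the sources used here. The medians of the 2 arrays were 36.4 and 37.9 and their trimmed means, with 2% of the values left out at each end, were 106 and 109. The 2 columns therefore had nearly equal levels, but whether they had been scaled to a common target is unknown. Detection calls for single probe sets were not used here.

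Each array held 45101 probe sets, of which 64 were controls of the manufacturer and were left out of all counts. Gene names came from the platform annotation of GEO. Of all probe sets, 34958 had 1 gene symbol, 932 had several and 9211 were not listed in that annotation and are unnamed here. Symbols were checked by Entrez gene identifier against the RefSeq gene table of the GRCm38.p6 assembly, which matched 34754 of the 34958 and changed 0 symbols. The other 204 kept the name of the annotation. No gene was named from a probe set with several symbols. No genome build is given in the sources used here, and no coordinates were used.

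The background bound of an array was the 95th percentile of the intensity of the probe sets for the genes of a first off-tissue list, made of genes of liver, eye, pancreas and kidney. It was 46.2 on set 1 and 52.7 on set 2. A probe set was called above background when it exceeded the bound on both arrays, and a gene when at least 1 of its probe sets did. The brightest probe set gave the level of a gene. Probe sets of a gene often disagreed, and the report gives their number for the named genes. A second off-tissue list, of other organs, checked the bound. The share of the first list above the bound is largely fixed by the way the bound was made. Intensities under 1 were set to 1 before the log2 was taken. Differences are log2 of set 2 minus log2 of set 1, less their median over the probe sets above background, which was 0.03.

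A set of 35 gene lists for T cell functions and other cell types was fixed before the data were examined, as were the bound, the fold limit, the rule for named genes and the alternatives, except where the closing section says otherwise. The lists held 726 different genes. Of these, 667 were matched to a probe set with 1 gene symbol, and the other 59 were not analysed here. Several lists share members. For each list the number of genes above background was set against 10000 random gene lists with the same numbers of probe sets per gene. The median difference between the arrays was taken for lists with at least 3 genes above background, leaving out both off-tissue lists. It was set against 10000 random lists matched on mean intensity, drawn from the 100 genes on either side of each member. The central 95% of the random lists is given as a range. Genes are not replicates, so these ranges describe the 2 arrays and are not tests. With 1 group of 2 arrays, no comparison between groups could be tested and no p-value for one is given, and the number of arrays limits the precision. In the closing section, 2000 shuffles of the differences among genes of like intensity show how far out the lists lie when genes vary independently, which was not tested.

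The rule for named genes had 4 parts. Every gene of an identity panel of T cell genes was given whatever its value. From each list, up to 3 genes with the highest mean intensity among those above background were eligible, and up to 3 genes not above background in alphabetical order. The 5 probe sets most above and the 5 most below on set 2 relative to set 1 were named, and so were the 10 named probe sets with the highest mean intensity. Genes named outside this rule are said to be chosen after their values were seen. Intensity depends on the probes as well as on the transcript, so levels of different genes are not comparable as abundances.

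The calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, and matplotlib 3.10.9 drew the plots. They were tested on simulated data. In a simulated comparison of the 2 arrays with 200 changed probe sets, 100% of the 3-fold and 100% of the 4-fold changes were found at the 2-fold limit, against 0.0225% of the unchanged probe sets. A simulated list of 20 genes lowered by 0.3 gave a median of -0.19, at percentile 0.26 of its random lists, and 4.5% of 400 unchanged lists lay outside the central range. Of 52 simulated absent genes 13.5% were above the bound, and of 28 simulated expressed genes 100% were. The simulated absent genes were drawn from the first off-tissue list, which also sets the bound. Their 13.5% is therefore largely set by construction and is no independent rate of false detection. The simulated expressed genes were set far above the bound, so their 100% was fixed in advance. The 3-fold and 4-fold changes were placed only in probe sets well above it. The simulated noise was drawn from a normal distribution with an SD set by intensity. In the real arrays 0.233% of probe sets above background differed over 2-fold, so 0.0225% cannot be taken as their rate of false calls. Detection of expressed genes or changes near the bound was therefore not tested.

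Alternatives were tried for the scaling between arrays, the log scale, the background bound, the probe sets that stand for a gene, the fold limit and the use of both arrays. The scaling alternatives were no centring, quantile normalization and a loess fit with a span of 0.3. Agreement was also computed over all probe sets other than controls.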

Results

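The study profiled the transcriptome of T cell blasts, with no second condition. The design leaves a pair of questions, which genes of T cell function were detectable in these cells and how closely the 2 arrays matched. The cells were mouse 5cc7 T cells, whose receptor recognises a peptide of moth cytochrome c, taken 5 days after stimulation with that peptide. The data comprised 1 group of 2 arrays, set 1 and set 2, with 45037 probe sets each after controls were left out. Median intensity was 36.4 on set 1 and 37.9 on set 2, and the highest intensities were 8860.2 and 8718.8. Values are given as the mean ± SD of the 2 arrays (n = 2) in the deposited linear intensity.

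Of the 45037 probe sets, 18064 (40.1%) exceeded the background bound on both arrays, and these represented 8990 of 18193 named genes (49.4%). On single arrays the counts were 19876 (44.1%) for set 1 and 18904 (42.0%) for set 2. Among the second off-tissue genes, which stand for transcripts of other organs, 9 of 52 (17.3%) were above background, against a random range of 16 to 29. The thyroid gene Tg was at 432 ± 18.7, and the next highest member, Pomc, was at 113 ± 7.42. In the first off-tissue list 3 of 45 genes exceeded the bound, with a random range of 12 to 25. These were the lens gene Bfsp2 and the liver genes Cyp2e1 and Tdo2. A gene above the bound but no brighter than Pomc is therefore weakly distinguished from an absent one, and Tg was brighter still. This limit covers genes named below such as Cd8a, Bcl6, Cd79a and H2-Ab1.

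The 10 named probe sets with the highest intensity were annotated to ribosomal proteins, a translation factor and a T cell receptor segment. They measured Rps18 at 8789.5 ± 100, Rps3 at 7758 ± 633, Rpsa at 7409 ± 282, Rpl37a at 7395 ± 540, Rpl38 at 7349 ± 276, Rps29 at 7234 ± 94.0, Rps3a1 at 7222 ± 354 and Rps19 at 7178 ± 29.6. The elongation factor Eef1a1 was at 7458 ± 753. Trbv1, annotated as a variable segment of the T cell receptor beta chain, was at 7345 ± 68.7. Which transcripts its probe set binds was not examined. All 14 measured housekeeping genes were above background (random range 5 to 12).

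Probe sets of a single gene did not always give the same call. Of 113 genes above background that the rule for named genes takes from the lists, 57 had more than 1 probe set, and in 34 of these every probe set was above background. In the other 23 the call rested on part of the probe sets. This was 1 of 2 for Cd22, Epcam, Gp1bb, Pomc and Rab8b, 1 of 3 for Ctsc, H2-Ab1, Mif and Tdo2, and 2 of 3 for Csf1r, Ikzf2, Rab8a, Tgfbr2 and Top2a. It was 2 of 4 for Il16 and Rab27a, 3 of 4 for Cd44, 2 of 5 for Cd8a, 5 of 6 for Maf, 4 of 6 for Rps18, 2 of 7 for Xiap, 6 of 9 for Rora and 5 of 11 for Ighm.

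**Figure D1:**
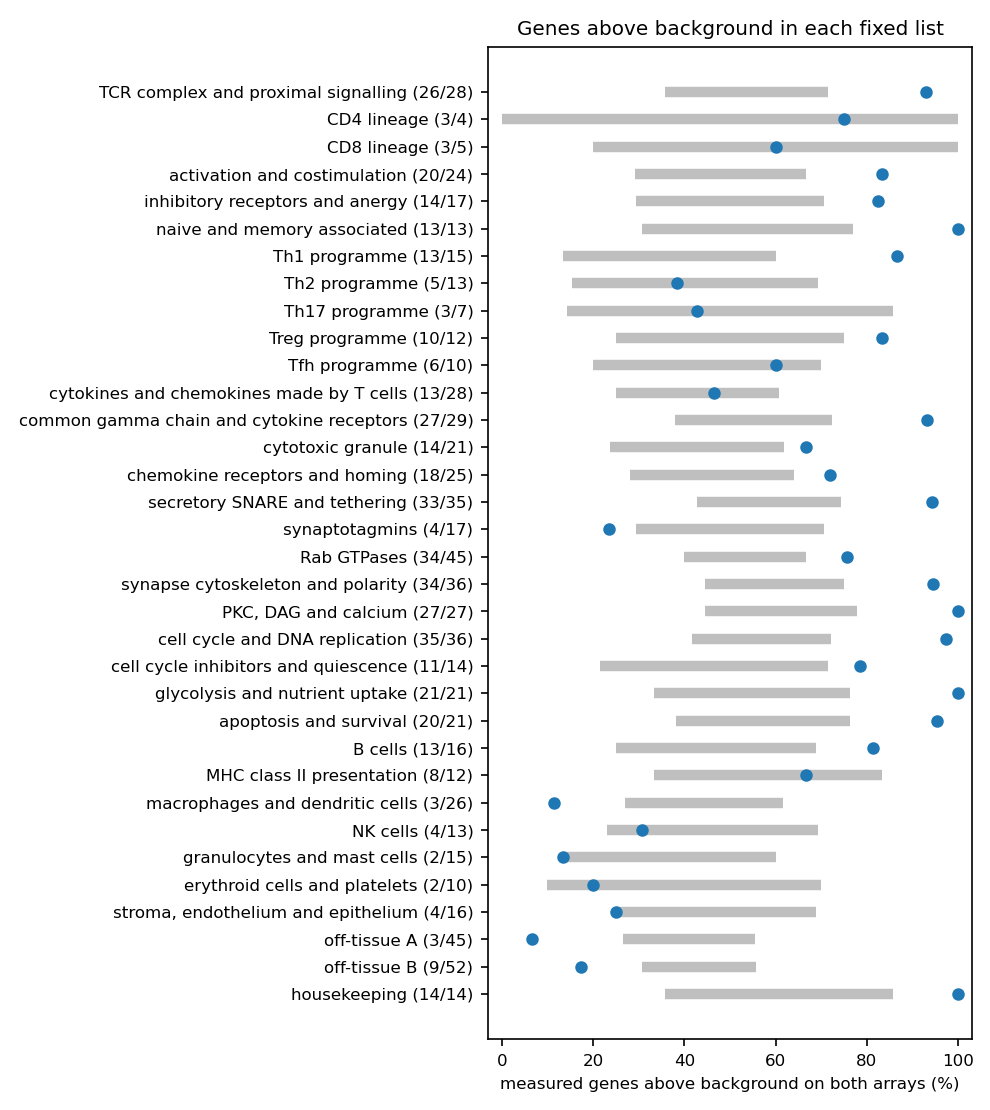
Percent of measured genes above background for each gene list, with blue dots for the measured percent and grey bars for the central 95% of 10000 random lists with the same numbers of probe sets. The T cell receptor list (26 of 28 genes) lies above its bar, and the macrophage and dendritic cell list (3 of 26) lies below it.

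Genes of the T cell receptor complex and its proximal signalling were nearly all detected. Of 28 measured genes 26 were above background, where random lists gave 10 to 20. The CD3 chains, which carry the receptor signal into the cell, were at 4671 ± 299 for Cd3d, 1398 ± 46.7 for Cd3e and 2843 ± 11.4 for Cd3g. The kinase gene Zap70 was at 906 ± 71.9, the phosphatase gene Ptprc (CD45) at 4892 ± 207 and Thy1 at 3449 ± 139. The 2 genes not above background were the adaptor gene Grap2 at 24.5 ± 10.7 and Tcra at 10.6 ± 4.45. Probe sets annotated to Trav9d-3, a receptor alpha chain segment chosen here after its values were seen, ranged from 40.55 ± 4.17 to 6445 ± 419. The low Tcra value therefore does not show that alpha chain transcripts were absent. Of 27 measured genes for protein kinase C, diacylglycerol and calcium signalling 27 were detected (random range 12 to 21). They included Dgkz and Dgka, kinases that consume diacylglycerol, at 3189 ± 60.0 and 2578 ± 146, and the potassium channel gene Kcnn4 at 1810.3 ± 130.1. Protein kinase C theta (Prkcq), a kinase of the immune synapse chosen here after its value was seen, was at 1435 ± 57.9.

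Lineage genes of CD4 T cells were above background in 3 of 4 cases (random range 0 to 4), with Cd4 at 1119 ± 95.2 and its lineage factor Zbtb7b at 408 ± 42.9. The exception was Cd40lg, the CD40 ligand of helper cells, at 41.1 ± 4.74. For the CD8 lineage 3 of 5 genes were above background (random range 1 to 5). Cd8b1 was at 213 ± 31.7 and Runx3 at 429 ± 19.4. Cd8a was at 66.5 ± 1.2, and 2 of its 5 probe sets exceeded the bound. Eomes and Crtam were not above background, at 23.4 ± 2.4 and 28.1 ± 0.566. Neither lineage list left its random range, but the lists are short. The range covered every possible count of the CD4 list and every count but 0 of the CD8 list. The ranges therefore say little about either lineage.

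**Figure D2:**
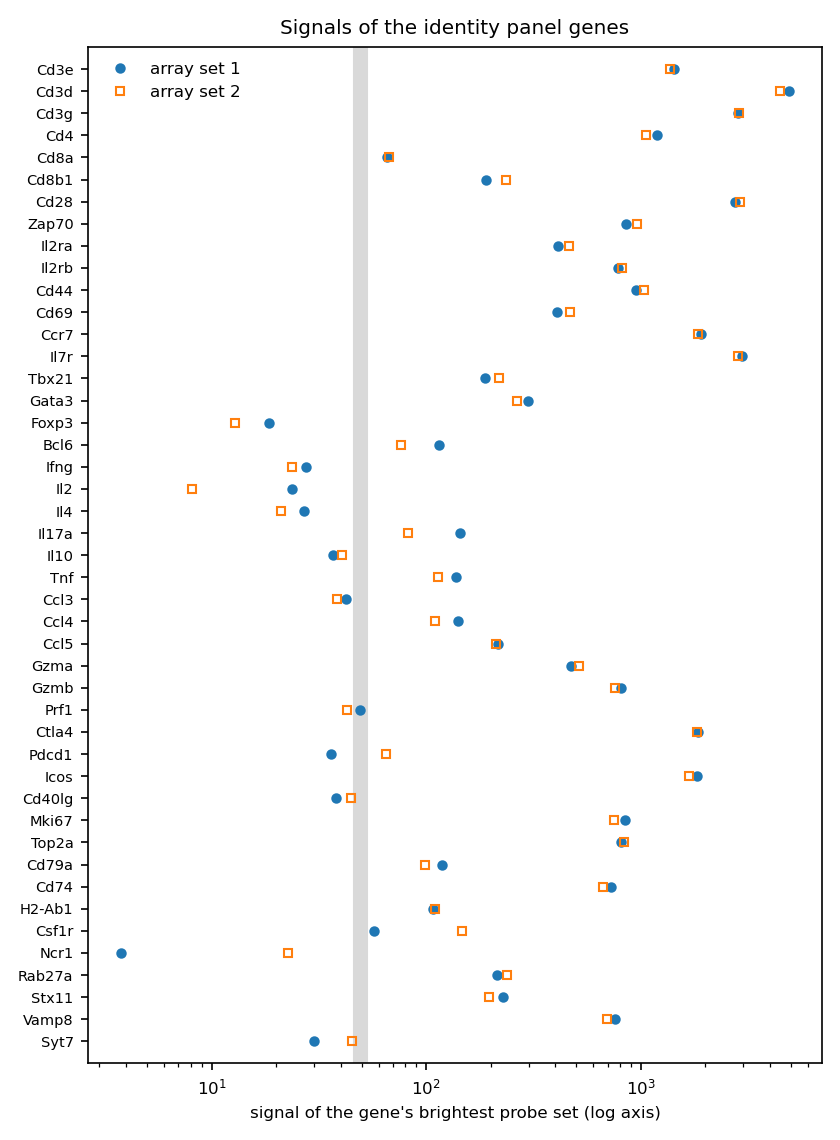
Intensity on set 1 and set 2 for each gene of the identity panel, in panel order on a log axis, with 1 point per array and a grey band between the 2 background bounds of 46.2 and 52.7. In the panel 34 of 45 measured genes are above background on both arrays, and Cd3d, Cd3g and Cd28 lie far above the band while Foxp3, Il2 and Ncr1 lie under it.

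Activation and costimulation genes were above background in 20 of 24 cases (random range 7 to 16). Cd28, the main costimulatory receptor, was at 2819 ± 122, Icos at 1754 ± 102 and Bhlhe40, a transcription factor of activated T cells, at 1628 ± 123. The interleukin 2 receptor chains Il2ra and Il2rb were at 437 ± 35.1 and 801 ± 25.2, Cd44 at 995 ± 61.1 and the early activation marker Cd69 at 436 ± 41.4. Rel and Tnfsf11 were not above background, at 46.7 ± 3.82 and 52.0 ± 19.2. Of the inhibitory receptors and anergy genes 14 of 17 were detected (random range 5 to 12), with Ctla4 at 1836 ± 12.1 and the ubiquitin ligase gene Cblb at 2043 ± 147. Pdcd1, which encodes PD-1, exceeded the bound on set 2 alone and so was not above background, at 50.4 ± 20.2, nor were Nt5e at 14.3 ± 13.4 and Rnf128 at 20.9 ± 0.919.

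Genes associated with naive and memory T cells were above background in 13 of 13 cases (random range 4 to 10). Satb1, a chromatin organiser, was at 3459 ± 264, the interleukin 7 receptor gene Il7r at 2894 ± 83.4 and the lymph node homing receptor gene Ccr7 at 1869 ± 42.1. Cytokine receptor genes were detected in 27 of 29 cases (random range 11 to 21), among them Tgfbr2 at 1072 ± 84.7 and the kinase gene Jak1 at 2577 ± 123. Ifngr2 and Il9r were not above background, at 42.4 ± 5.94 and 4.1 ± 1.27. For apoptosis and survival 20 of 21 genes were above background (random range 8 to 16), with Mcl1, which opposes apoptosis, at 2353 ± 173, and the pro-apoptotic Bcl2l11 at 893 ± 92.3. Casp9 was not, at 38.2 ± 5.73.

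Among the helper programmes, 13 of 15 genes of the Th1 list were above background (random range 2 to 9). Tbx21, the Th1 master factor T-bet, was at 203 ± 20.6, the chemokine receptor gene Cxcr3 at 1125 ± 64.4 and Stat4, which acts downstream of interleukin 12, at 987 ± 120.1. The signature cytokine gene Ifng was not above background at 25.6 ± 2.55, nor was Hlx at 4.2 ± 1.41. In the Th2 list 5 of 13 genes were above background (random range 2 to 9), a count that rose to 8 with the bound at the 90th percentile. Gata3, the Th2 factor, was at 281 ± 22.6, Maf at 601 ± 90.2 and Stat6 at 589.6 ± 31.0, while Ccr4 and Ccr8 were not above background at 34.8 ± 15.2 and 38.4 ± 3.32. The Th17 list had 3 of 7 genes above background (random range 1 to 6). These were Rora at 619 ± 44.3, Ccr6 at 308 ± 44.8 and the cytokine gene Il17a at 112 ± 43.3, whose level differed between the arrays (143 and 81.8). Ahr, Ccl20 and Il1r1 were not above background.

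Regulatory T cell genes were above background in 10 of 12 cases (random range 3 to 9). Tnfrsf18 was at 947 ± 80.5 and Ikzf2 at 534 ± 15.3, but Foxp3, the lineage factor of regulatory T cells, was not above background at 15.8 ± 4.03, nor was Gpr83 at 50.5 ± 2.33. Of the follicular helper genes 6 of 10 were detected (random range 2 to 7). Bcl6, the factor of that lineage, was at 95.4 ± 26.9, Btla at 649.8 ± 7.92, Sh2d1a at 569.6 ± 14.2 and Pou2af1 at 269.9 ± 9.69. Ascl2, Cxcl13 and Il21 were not above background.

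Of the cytokine and chemokine genes 13 of 28 were above background, within the random range of 7 to 17. Lymphotoxin beta (Ltb) was at 3441 ± 38.1, Mif at 3151 ± 333 and Il16 at 1216 ± 55.0. Tnf was at 125 ± 17.2 and the chemokine genes Ccl4 and Ccl5 at 125 ± 21.8 and 213 ± 4.31. The cytokine genes Il2, Il4 and Il10 were not above background, at 15.8 ± 11, 24.1 ± 4.17 and 38.5 ± 2.69. Neither were the chemokine genes Ccl3 at 40.5 ± 2.9, Ccl1 at 31.9 ± 3.82 and Ccl9 at 24.6 ± 6.08. Chemokine receptor and homing genes were above background in 18 of 25 cases (random range 7 to 16), with the integrin gene Itgal at 2329 ± 153 and the selectin ligand gene Selplg at 2214 ± 168. Ccr10 and Ccr3 were not, at 4.85 ± 0.0707 and 3.95 ± 1.06.

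Cytotoxic granule genes were above background in 14 of 21 cases (random range 5 to 13). The granule proteoglycan gene Srgn was at 3403 ± 139, Ctsc, which activates granzymes, at 968 ± 15.3 and Lamp1 at 823 ± 22.8. Granzyme genes Gzma and Gzmb were at 495 ± 31.1 and 781 ± 37.5. The perforin gene Prf1 exceeded the bound on set 1 alone and so was not above background, at 45.8 ± 4.45, and neither were Gzmd, Gzme and Gzmf.

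The secretory machinery that carries cytokines and granules to the cell surface was broadly detected. Of the SNARE and tethering genes 33 of 35 were above background (random range 15 to 26), with Vamp8 at 726 ± 46.7, Stx5a at 713 ± 57.7, Vti1b at 577 ± 14 and Stx11 at 212 ± 21.9. Snap25, a neuronal SNARE, and Vamp5 were not, at 8.3 ± 6.65 and 35.4 ± 1.2. Rab GTPase genes, which direct vesicle traffic, were above background in 34 of 45 cases (random range 18 to 30). They included Rab8b at 1553 ± 63.9, Rab8a at 1528 ± 79.8, Rab7 at 1279.8 ± 74.5 and Rab27a, which is needed for granule release, at 226 ± 18.0, but not Rab13, Rab17 or Rab20. Synaptotagmin and synaptotagmin-like genes, many of which encode calcium sensors of vesicle fusion, stood below their random range of 5 to 12, with 4 of 17 above background. These were Sytl2 at 374 ± 30.3, Syt11 at 152 ± 13.6, Sytl1 at 150.2 ± 8.7 and, chosen after its value was seen, Syt1 at 52.6 ± 6.51, for which 1 of 4 probe sets was above background. Syt7, implicated in lysosome exocytosis, was not above background at 37.5 ± 10.5, and Syt10, Syt12 and Syt13 were not either.

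Cytoskeleton and polarity genes of the immune synapse were above background in 34 of 36 cases (random range 16 to 27). Coronin 1A (Coro1a), cofilin (Cfl1) and the Arp2/3 subunit gene Arpc2, which act on actin filaments, were at 4391 ± 155, 3977 ± 48.9 and 3381 ± 40.7. The polarity gene Pard3 was not above background at 32.4 ± 1.13.

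Genes of division and glycolysis were above background in nearly every case. Of 36 cell cycle and DNA replication genes 35 were detected (random range 15 to 26), with the replication genes Pcna and Mcm7 at 2996 ± 213 and 1396 ± 14.6, the cyclin gene Ccnd2 at 1724 ± 48.8, Top2a at 819 ± 17.2 and the proliferation marker Mki67 at 798 ± 66.9. The exception was Tyms at 29.2 ± 3.54. Cell cycle inhibitor and quiescence genes were above background in 11 of 14 cases (random range 3 to 10), among them Btg1 at 4316 ± 222, Slfn2 at 1689 ± 20.7 and Btg2 at 1674 ± 158. Cdkn1c, Cdkn2a and Cdkn2b were not above background. All 21 measured glycolysis and nutrient uptake genes were detected (random range 7 to 16), with Pgk1 at 6873 ± 279, Ldha at 4823 ± 251 and Aldoa at 4493 ± 508.

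Markers of other cell types gave unequal results. B cell genes were above background in 13 of 16 cases (random range 4 to 11). The immunoglobulin heavy chain gene Ighm was at 2372 ± 295, though 5 of its 11 probe sets exceeded the bound, and Ms4a1 (CD20) was at 377 ± 17.4, Cd22 at 221 ± 10.04 and Cd79a at 108 ± 14.1. Cr2, Ebf1 and Fcer2a were not above background. In the MHC class II list 8 of 12 genes were above background (random range 4 to 10), with Cd74, the invariant chain, at 694 ± 41.1, H2-Oa at 432 ± 30.8, H2-Eb1 at 363 ± 5.94 and H2-Ab1 at 109 ± 1.41. Cd40, Cd86 and Ciita were not. The MHC class II count fell to 5 when the median over a gene's probe sets gave its level.

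Macrophage and dendritic cell genes were above background in 3 of 26 cases (random range 7 to 16). These were the protease gene Ctss at 1086 ± 199, Csf1r at 102 ± 63.2 and Lyz2 at 55.5 ± 11.7, while Adgre1, C1qa and C1qb were not above background. The count was 5 on either array alone, and 8 with the bound at the 90th percentile or at the median of all probe sets. Of the NK cell genes 4 of 13 were above background (random range 3 to 9). They were the lectin receptor genes Klrd1 at 1629.9 ± 75.1 and Klrk1 at 460.2 ± 15.6, together with Il2rb and, chosen after its value was seen, Klrc1 at 223 ± 19.9. Ncr1, a receptor typical of NK cells, was not above background at 13.2 ± 13.4, and Cd244a, Klra1 and Klra7 were not either.

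Granulocyte and mast cell genes were above background in 2 of 15 cases (random range 2 to 9), Ngp at 63.8 ± 4.24 and Cma1 at 53.5 ± 9.55. In the erythroid and platelet list 2 of 10 genes were (random range 1 to 7), Itga2b at 80.4 ± 18.7 and Gp1bb at 58.8 ± 9.55. Both counts fell to 0 with the bound taken from the second off-tissue list. Stroma, endothelium and epithelium genes were above background in 4 of 16 cases (random range 4 to 11), with Pecam1 at 326 ± 36.8, Epcam at 189.8 ± 21.1 and Kdr at 67.0 ± 0.0707. This count fell to 2 with the same bound. Of 4 sex-linked genes 1 was above background, Xist at 3480.4 ± 305, the transcript of the inactive X chromosome, and the Y-linked genes Kdm5d, Eif2s3y and Uty were not above background.

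**Figure D3:**
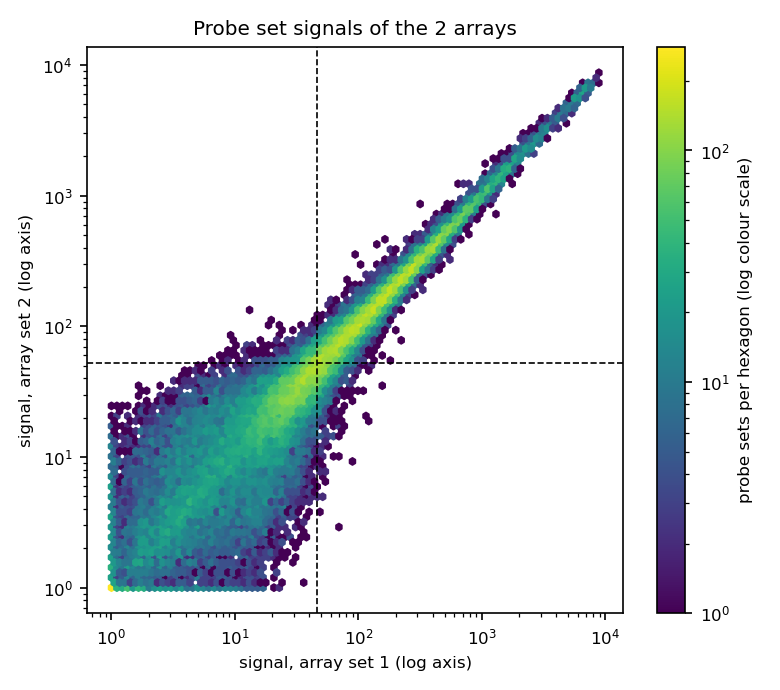
Intensity of each probe set on set 1 (horizontal) against set 2 (vertical), both on log axes, with dashed lines at the background bounds of 46.2 and 52.7 and intensities under 1 drawn at 1. Above the bounds 99.8% of probe sets lie within 2-fold of each other, and the scatter widens below them.

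The 2 arrays gave similar intensities for genes above background. Across these 18064 probe sets, which are not independent replicates, Pearson's r of log2 intensity was 0.985 and Spearman's rho 0.972. The SD of the log2 difference was 0.25, and 96.8% of probe sets lay within 1.5-fold. Only 36 probe sets had identical values, so the 2 columns are not copies. Among all probe sets, including those not above background, the spread narrowed with intensity. The SD was 1.2 for probe sets under 32, 0.46 for those between 32 and 64 and 0.12 for those above 2048. Over all 45037 probe sets the SD was 0.86 and Pearson's r was 0.941. Ratios of the 3' to the 5' control probe sets, a measure of RNA integrity, were taken on set 1 and set 2. They were 1.09 and 1.14 for beta-actin, 0.737 and 0.752 for Gapdh and 3.95 and 3.79 for the transferrin receptor. The 5' probe set of the transferrin receptor read 51.3 and 53, close to the bounds of 46.2 and 52.7. Its ratio is therefore a weak measure of integrity.

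More than 2-fold differences between the arrays were found for 42 of the 18064 probe sets (0.233%), 33 higher on set 2 and 9 lower. The 5 most raised on set 2 were E2f5, an E2F transcription factor gene (96.3 on set 1 and 344.1 on set 2, log2 difference 1.80), a probe set for the ribosomal gene Rpl37a (139.2 and 408.5, 1.52), the unnamed 1447205_x_at (101 and 294.3, 1.51), Fbxo36 (162.9 and 452.1, 1.44) and Adam4 (58.3 and 155.5, 1.38). The 5 most lowered were Ifit1bl2 (185.7 and 56.5, -1.75), Vps8 (222.6 and 77.5, -1.55), Slc38a10 (138.2 and 54.4, -1.38), the unnamed 1419982_s_at (151.5 and 59.7, -1.38) and Marchf10 (128.8 and 56.8, -1.21). Of the 42 probe sets, 38 had a mean intensity under 256. The Rpl37a probe set is 1416218_x_at, a different one from the probe set of that gene among the 10 brightest. With 1 array per set these differences have no replicate check. Their number depended on the limits chosen, at 581 for a 1.5-fold and 2 for a 3-fold limit, and at 8 on the log2(intensity + 50) scale.

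Most gene lists did not differ between the arrays beyond random lists of like intensity, and 4 of 30 lay outside the central 95%, where 1.5 would by chance. The cytokine and chemokine list had a median log2 difference of -0.23 (random range -0.15 to 0.11), with 11 of 13 genes lower on set 2, at percentile 0.055 of its random lists. The Th1 list was at -0.13 with 9 of 13 genes lower, and the homing list at -0.11 with 14 of 18 lower. These lists share members, such as Cxcr3 in the last pair. Such shares of lower genes were not particular to them, since the naive and memory list also had 11 of 13 genes lower, at percentile 41.2. The macrophage and dendritic cell list was at 0.40, with its 3 detected genes higher on set 2. The probe sets of Csf1r disagreed, since 1 read 57.3 and 146.7 and another 103.4 and 100.4, but the list stayed outside its central range, at 0.34, with the median over a gene's probe sets. The list kept 2 detected genes, too few for a value, with the bound at the 99th percentile or from the second off-tissue list. With the bound at the 90th percentile or at the median of all probe sets it held 8 genes, at 0.37 in both cases. The genes added there were not above the main bound, where the scatter is wide. The Th1 list returned to its central range on the log2(intensity + 50) scale (percentile 8.37) and with the median over a gene's probe sets (11.9), and the homing list did with that median (6.52). Those 2 lists also did so with other settings given in the closing section. The count of lists outside fell to 2 with the bound at the 99th percentile, with the bound from the second off-tissue list and with the median over a gene's probe sets.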

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

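The tests below were chosen after the result was seen, except the test of chance among the lists compared, and so were Klrc1, H2-Aa, H2-Ea, Tyrobp and Fcer1g. Other cells in the culture are weighed as a technical source. No biological explanation within the 5cc7 cells was tested, since the design has 1 group.

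The first pattern is the detection of B cell marker genes, with 13 of 16 above background. The share of the list above background was 81.25%, against 17.3% of the second off-tissue list, whose genes stand for absent transcripts. That share is the pattern itself, so it gives no separate test of background hybridisation. At the main bound, carry-over of macrophages is argued against by the macrophage and dendritic cell list, of which 11.5% was above background. That count of 3 of 26 was higher on either array alone. It was 8 with the bound at the 90th percentile or at the median of all probe sets. Residual B cells in the culture stay open as a source and were not shown, since 4 of 4 abundant B cell transcripts of antigen presentation were above background but the MHC class II list, at 8 of 12, lay within its random range of 4 to 10. The 4 were Cd74 at 694 ± 41.1, H2-Eb1 at 363 ± 5.94, H2-Aa at 237 ± 33.4 and H2-Ab1 at 109 ± 1.41. The probe sets above background were 1 of 3 for H2-Ab1, 3 of 4 for H2-Aa and 0 of 3 for H2-Ea, the number of the list's genes that T cells also express was not tested and the labels name no purification step.

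The second pattern is the lower intensity of the cytokine and chemokine list on set 2. Chance among the 30 lists is argued against if genes vary independently, since some list lay as far out in 2.9% of 2000 shuffles of the differences among genes of like intensity. Genes that vary together would make such a result more frequent, and 5.3% of the shuffles put as many lists outside the central range as observed. Noise of dim probe sets stays open. The 6 members brighter than 4 times the bound were all lower on set 2, with a median of -0.14, but this was at percentile 7.21 of random lists of like intensity. The brightest probe sets in general were slightly lower on set 2, with a median log2 difference of -0.06 before centring for those above 2048.

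The third pattern is the detection of Klrd1, Klrk1 and Klrc1 without most other NK cell genes. Contaminating NK cells are argued against by their abundant adaptor genes Tyrobp and Fcer1g, whose highest intensity on either array was 37.2, under the lower bound of 46.2. Carry-over of CD8 T cells cannot be told apart from expression by the 5cc7 cells, since the CD8 lineage genes went both ways. Of the 5 Cd8a probe sets 2 were above background, at 59.15 ± 8.56 and 66.5 ± 1.2, and Cd8b1 was at 213 ± 31.7, but Eomes and Crtam were not above background at 23.4 ± 2.4 and 28.1 ± 0.566.

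Signals also appeared in probe sets that the report's lists do not use. Of the probe sets unnamed here 2219 were above background, and of those with several gene symbols 488 were. The manufacturer's control probe sets for mouse repeat sequences had mean intensities of 7129 for MURINE_B2, 1383 for MURINE_b1 and 393 for MUR_b2, above the background bound.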

How the results depend on the processing

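The bound from olfactory receptor genes and the run without Csf1r were chosen after seeing the data. No paired analysis was possible because the 2 arrays form 1 group.

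The between-array SD of 0.25 became 0.18 on the log2(intensity + 50) scale and 0.86 over all probe sets. By the construction of these settings, the offset shrinks and the dim probe sets widen it. For the 42 differences over 2-fold, the count was 8 with the offset of 50, 74 with the bound at the 90th percentile, 19 with that from the second off-tissue list, 70 with that at the median, 581 at 1.5-fold and 2 at 3-fold. The count of 4 lists outside the random range became 2 with the bound at the 99th percentile, 2 with that from the second off-tissue list and 2 with the median over a gene's probe sets. The causes of the list changes were not tested.

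Genes above background by list changed as follows. With the bound at the 90th percentile, Th2 rose to 8 and macrophages and dendritic cells to 8. With the bound at the median of all probe sets, macrophages and dendritic cells rose to 8. With the 99th percentile, granulocytes and mast cells fell to 1, erythroid cells and platelets to 1 and the first off-tissue list to 0. With the second off-tissue list, these 3 fell to 0, 0 and 0, stroma to 2 and the second off-tissue list itself to 2. With the olfactory bound, granulocytes and mast cells and erythroid cells and platelets fell to 1 and 1. With the median over a gene's probe sets, MHC class II fell to 5 and erythroid cells and platelets to 1. Leaving out 1 array gave 5 to 5 for macrophages and dendritic cells and 2 to 4 for granulocytes and mast cells. The other 332 of 350 list counts were within 1.5 times.

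The cytokine list's difference stayed negative under every alternative run, from -0.23 to -0.13, at percentiles from 0.01 to 1.77. The Th1 list also reached percentile 3.93 with the 99th percentile bound and with the second off-tissue bound, and the homing list 2.64 with loess, 2.95 with the 90th percentile and 2.87 without x_at and s_at probe sets. The macrophage list had 2 genes and no value without Csf1r and with the bounds from the 99th percentile, the second off-tissue list and the olfactory receptor genes. Of 353 list differences 331 moved by less than the SD of their random lists, 22 by more, and 0 called differences changed sign. Of 40 named differences 31 moved by less than the between-array SD, 9 by more, and 0 changed sign. Of 192 named genes 113 were above background, 95 of them under all 10 alternatives, and 60 were above under none. Intensities near the bound limit these calls, with an SD of 0.46 between 32 and 64.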

Other observations

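The gene families and genes in this part and their comparison with random lists were chosen after values were seen. All 8 measured Gimap genes, GTPases of lymphocytes, were above background (random range 1 to 6), with Gimap4 at 4183 ± 149 and Gimap6 at 2031 ± 44.8. The 5 measured guanylate-binding protein genes, which interferons induce, were all above background (random range 0 to 4), with Gbp2 at 1148 ± 63.9. Of 40 genes with the symbols of proteasome subunits 37 were detected (random range 14 to 26), including Psmb8, a subunit of the immunoproteasome, at 2714 ± 70.1. Psmc3ip, which is no proteasome subunit, was among the 3 that were not. Genes with the symbols of respiratory chain and ATP synthase subunits were above background in 76 of 86 cases (random range 35 to 53), with Atp5g3 at 3282 ± 113. These include 8 assembly factors of complex I, which are no subunits, 7 of them above background. The CCT chaperonin, which folds actin and tubulin, had 7 of 8 genes above background (random range 2 to 7), with Cct2 at 2973 ± 87.8.

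Other families were mostly not detected. Hox genes were above background in 2 of 33 cases (random range 9 to 20), with Hoxa5 at 143 ± 38.3, and olfactory receptor genes in 3 of 38 (random range 8 to 20). Voltage-gated sodium channel genes were in 0 of 11 (random range 4 to 9) and keratin genes in 7 of 48 (random range 13 to 25), with Krt42 at 296 ± 2.47. Of the Toll-like receptor genes 3 of 11 were above background (random range 2 to 8), with Tlr1 at 123 ± 4.6.

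Probe sets annotated to Trav9d-3, a variable segment of the T cell receptor alpha chain, differed widely. The probe set 1426113_x_at read 6741 on set 1 and 6149 on set 2, and 1452405_x_at and 1426168_a_at had means of 6098 and 5613. The probe set 1427653_at had a mean of 304, and 1427766_at read 37.6 and 43.5. Which transcripts each probe set binds was not examined.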
